A study of Homo sapiens with 4 samples.

How the data were processed

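RNA of MHCC97H and MHCC97L cells transfected with PML siRNA was compared with RNA of control cells of the same line on two-colour 35K human oligonucleotide arrays, 2 arrays per line. Per the labels' protocols, total RNA was extracted with Trizol, amplified, and labelled with Cy5 (siRNA) or Cy3 (control) using Klenow enzyme, with no dye swap. The labels describe the control in one field as transfected with empty vector and in another with control siRNA, and the series' design text names 1 control and 1 transfected culture per line. Whether the arrays of a line are separate cultures or repeat hybridisations is therefore open.

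Per the file headers, the deposited files of each array are LuxScan scanner output with spot and local background intensity for Cy5 and Cy3, not background-subtracted and not normalized. They also hold a deposited log10 ratio column, which equals the log10 of the spot medians' ratio. The deposited value table holds log10 ratios of Cy5 over Cy3 made by the authors, with column medians of 0.00372, 0.00672, 0.00262 and 0.00589. Its scale and direction were found by comparison with the scanner values, and its centring and normalization method are not given in the sources used here. The column of each MHCC97H sample matched its own scanner file (r = 0.917 and 0.938 at bright spots). Those of MHCC97L matched the other MHCC97L scanner file (r = 0.981 and 0.947, against 0.393 and 0.367 for their own). The scanner files were used as labelled, and the value table served as an alternative.

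Spot median intensities were background-corrected with normexp and an offset of 50, and normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. A spot was taken as above background where its median exceeded the local background median by more than 2 SD of the local background. At most 0.208% of the 480 blank spots met this in any channel. Spots above background in at least 1 channel on at least 2 arrays were kept, 17078 of 37632. Of the gene spots, 18651 had a current symbol as their name, 3781 an older symbol, 818 a protein accession that matched the RefSeq gene table, 3070 another name, which was kept, and 9844 no name. The latter were not tested. For genes with several kept probes (2021 genes) the probe with the highest mean intensity was used, which gave 11636 genes. Up to 9 gene spots per channel of an array were at the scanner's ceiling. The brightest and second probes of a gene correlated across genes with r between 0.226 and 0.71 on the 4 arrays. The depth of an array has no count, so only the number of arrays and the signal over background limit the precision.

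Before the data were examined, the lists, the rule for named genes, the tests and most alternatives were fixed. The log2 ratios of all 4 arrays were fitted with a coefficient per line and 1 shared spread (lmFit and eBayes), testing each line against 0 and their difference. Changes common to both lines were tested on the means of the 2 lines. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. The 37 gene lists were tested with camera at a preset correlation of 0.01 and with an estimated one, with adjustment over the 37 lists. With an estimated correlation the degrees of freedom come from the arrays and are few. A list can then fail for the number of arrays alone, so that version cannot decide whether a shift reflects correlated genes. Where the genes of a list are more correlated than the preset value, the preset p-value is too small. The named genes were PML, the 10 genes with the largest and the 10 with the smallest ratios per line among those called, with one sign on both arrays, detected in at least 1 channel on every array and carrying a gene symbol. For both lines together they were the 10 largest in each direction by the smaller of the 2 lines' ratios with one sign on all 4 arrays, and for each described list up to 2 highest and 2 lowest members. Since the fit over all arrays called no gene in either line, the rule was applied to the fit of MHCC97H alone and to each MHCC97L array fitted without the other, a step decided after this was seen. Where a channel was not above background, the fold sets the brighter channel's normalized log2 value against the higher of 2 values. These are the lowest signal above background on that array and the dim signal itself. Where the dim signal was the higher, the fold is the plain ratio. The true dim signal may be higher, so such folds are uncertain and are not lower limits. They are also open to dye bias.

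The test was tried on simulated log2 ratios for 11636 genes with 200 changed. For MHCC97H with all 4 arrays it recovered 0.0%, 13.4% and 89.4% of genes changed by 0.5, 1 and 2 on the log2 scale, and for MHCC97L 0.0%, 16.4% and 95.5%. For MHCC97H without MHCC97L replicate 2 it recovered 38.8%, 100% and 100%. For the line means it recovered 14.9%, 92.5% and 100%. In these simulations 9, 2, 10 and 9 unchanged genes were called. A simulated list shift was found by camera with 0 other lists called. In it the genes were independent and every array had the same spread. It therefore cannot show how the preset correlation serves lists of correlated genes or arrays of unequal spread.

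Alternatives were the background correction, the normalization, the filter on dim probes, the summary of probes, the deposited ratios, the model of the spread, the scan day as a block, a size rule and leaving out each array in turn. Spot means, loess within print blocks, and the use of the fits without an MHCC97L array to name genes were chosen after seeing the data. PML was outside the tested genes because its probes did not pass the filter. Figures were drawn with matplotlib 3.10.9.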

Results

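Expression was measured on two-colour oligonucleotide arrays in a pair of human hepatocellular carcinoma lines, MHCC97H and MHCC97L, which derive from one parental line and are known for high and low metastatic capacity. Cells of each line were transfected with a small interfering RNA against PML, the protein that organises PML nuclear bodies, and were compared with control cells of the same line. Each line was hybridised on 2 arrays, so 4 arrays carried 37632 spots each, with siRNA RNA in the Cy5 channel and control RNA in the Cy3 channel on every array. Values are log2 ratios of siRNA over control. The share of gene spots above local background lay between 35.0% and 43.5% in the siRNA channel and between 36.0% and 47.2% in the control channel. The number of arrays limits the precision. The labels do not say that the arrays of a line came from separate cultures, so p-values of genes measure the spread between arrays, which may be technical. Each ratio is taken against the control channel of its own array, and the labels do not say whether the control RNAs of a line were separate. P-values of gene lists with the preset correlation measure the spread across genes.

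PML, the targeted gene, could not be measured. Its 2 probes were close to background in both lines. Probe 5370 was above background in 0 of 4 channel readings in MHCC97H and in 1 of 4 in MHCC97L, with mean log2 ratios of -0.03 ± 0.52 (SD, n = 2) and -0.04 ± 0.26 (SD, n = 2). Probe 20046 was above background in 1 of 4 readings in MHCC97H and 0 of 4 in MHCC97L, with mean log2 ratios of 0.04 ± 0.15 (SD, n = 2) and -0.37 ± 0.06 (SD, n = 2). No fold is given, since these spots hold background in most channels. A loss of PML transcript was therefore not detectable on these arrays, and the labels of the siRNA and control channels have no check from the target.

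The first comparison asks which transcripts differed between siRNA and control cells of MHCC97H. In a fit of the MHCC97H arrays on their own, the metallothionein genes MT2A and MT1X on chromosome 16, which encode metal-binding proteins, rose to 3.45-fold and 2.59-fold. Their log2 ratios were 1.79 ± 0.92 and 1.37 ± 0.91 (SD, n = 2). ENO2, a glycolytic enolase, rose 2.27-fold and CRABP2, a retinoic acid binding protein, rose 2.31-fold. ALB, the gene of serum albumin, fell by 1.24 ± 0.22 on the log2 scale (SD, n = 2), but had a ratio of 0.40 on MHCC97L replicate 1. The alcohol dehydrogenase gene ADH1A fell by 1.26 ± 0.12 (SD, n = 2). The aldehyde dehydrogenase gene ALDH3A1 fell by 1.25 ± 0.12 (SD, n = 2) at its brightest probe, while the mean ratios of its 3 kept probes reached up to -0.11. The list of hepatocyte genes did not pass in MHCC97H over all 4 arrays (median -0.08 over 25 members, camera adjusted p = 0.539 with the preset correlation). In the fit of MHCC97H alone 3 of its members rose and 4 fell.

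The other genes with the largest increases in MHCC97H were CD79A (log2 ratio 1.76), TCF7L2 (1.69), TEX101 (1.65), COXFA4L3 (1.42), HORMAD1 (1.19) and SLC6A8 (1.18). CD79A encodes a chain of the B cell receptor complex, TCF7L2 a transcription factor of the Wnt pathway and SLC6A8 a creatine transporter. The remaining largest decreases were SPTSSB (-1.45), VSIG1 (-1.34), TMEM30A (-1.29), MALL (-1.23), PABPC1 (-1.18), PEBP1 (-1.18) and IDH3G (-1.17). PABPC1 encodes the cytoplasmic poly(A) binding protein and IDH3G a subunit of mitochondrial isocitrate dehydrogenase. All 20 of these genes had limma adjusted p-values between 0.00297 and 0.0243 in that fit and the same sign on both MHCC97H arrays. Except for MT2A, MT1X, ADH1A, ALDH3A1, MALL and SLC6A8, each rests on 1 kept probe, and the second probe of SLC6A8 gave 0.40. On 1 MHCC97H array the control signal of COXFA4L3 and the siRNA signal of TMEM30A were not above background, so their ratios are uncertain.

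The fit of MHCC97H alone called 941 genes, 404 higher and 537 lower, at an adjusted p under 0.05, of 11636 genes tested. It was listed as an alternative before the data were examined. The planned fit over all 4 arrays, with 1 spread shared by both lines, called 0 genes in MHCC97H with limma, with 1099 genes at an unadjusted p under 0.05 where 582 would be expected by chance and a smallest adjusted p of 0.427. The 2 MHCC97L arrays differ from each other and set that shared spread, and no gene named for MHCC97H passed in that fit. Leaving out either MHCC97H array also gave 0 calls.

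Among the 37 gene lists fixed before the data were examined, 4 shifted upwards in MHCC97H in the fit over all 4 arrays by limma's camera test with a preset inter-gene correlation. No list member was called in that fit, so the counts of members that rose or fell below come from the fit of MHCC97H alone. Ribosomal protein genes had a median log2 ratio of 0.29 over 32 measured members (adjusted p = 4.93e-06, and adjusted p = 0.933 with an estimated correlation). Of these, 8 rose, 1 fell and 23 did not pass, and adjusted over the list alone 17 rose and 2 fell. RPS27 (0.69) and RPL27 (0.64) rose and RPS15 (-0.44) fell, while RPS2 had a ratio of -0.30 that did not pass. The hypoxia and glycolysis list had a median of 0.19 over 29 members (adjusted p = 0.00723, and adjusted p = 0.933 with an estimated correlation), of which 7 rose, 0 fell and 22 did not pass, with 10 up and 1 down adjusted over the list alone. Its leading members were ENO2 (1.18) and NDRG1 (1.15), a stress-responsive gene, and PGAM1 (-0.40) and PFKP (-0.23) had negative ratios that did not pass. On MHCC97H replicate 1, median centring in place of loess took this list's median from 0.05 to just under 0. Near-identical ribosomal pseudogenes make single ribosomal members uncertain, and the ribosomal median of MHCC97L replicate 2 turned from 0.09 to -0.05 with median centring. The 48 control spots of the ribosomal gene RPS9 had medians of 0.03 and 0.11 on the MHCC97H arrays, below the list's 0.31 and 0.26. The control spots of ACTB (0.21 and 0.27), GAPD (0.26 and 0.30, some at the scanner's ceiling) and LDHA (0.44 and 0.61) were higher.

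Mesenchymal and EMT genes had a median of 0.30 over 20 members (adjusted p = 0.0128, and adjusted p = 0.933 with an estimated correlation). Of these, 3 rose, 0 fell and 17 did not pass, with 11 up and 1 down adjusted over the list alone. THBS1, thrombospondin, rose by a log2 ratio of 0.55 ± 0.03 (SD, n = 2), while TWIST1 (-0.34) and MMP2 (-0.20) did not pass. TGF-beta responsive genes had a median of 0.20 over 21 members (adjusted p = 0.0164, and adjusted p = 0.933 with an estimated correlation), of which 5 rose, 0 fell and 16 did not pass, with 6 up and 0 down adjusted over the list alone. TGFB1 (0.91) rose, and SMAD6 (-0.12) and TGFBR2 (-0.12) did not pass. In the fit of MHCC97H alone, S phase and DNA replication genes also shifted down, with a median of -0.10 over 36 members (adjusted p = 0.00851, and adjusted p = 0.834 with an estimated correlation), led by falls of MCM7 (-0.71) and MCM3 (-0.60), subunits of the replicative helicase. CCNE1 (0.34) and CDC7 (0.18) had positive ratios that did not pass. With 5 members down, 0 up and 31 not passing, 6 fell adjusted over the list alone. With an estimated correlation no list passed in MHCC97H. Mesenchymal and EMT genes had an estimated correlation of 0.00637, below the preset 0.01, yet their camera p went from 0.00103 to 0.0774. The few arrays thus limited that version for this list, so a miss in it does not by itself show that correlated genes made a shift. The estimates for hypoxia and glycolysis (0.115), ribosomal protein (0.0979) and TGF-beta responsive genes (0.0512) were above the preset 0.01. If genes are that correlated, the preset p-values of these lists are too small. The number of shifted lists also depended on which array was left out. With the deposited log ratio, taken relative to the median of all genes, the medians on the MHCC97H arrays were 0.46 and 0.53 for ribosomal protein genes (0.31 and 0.26 after loess), 0.19 and 0.43 for hypoxia genes (0.05 and 0.27) and -0.03 and -0.13 for S phase genes (-0.11 and -0.19).

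The second comparison asks the same of MHCC97L, where the arrays gave different pictures. On MHCC97L replicate 1 the changes resembled those in MHCC97H: MT2A rose to 5.05-fold, TEX101 to 3.86-fold and CRABP2 to 3.23-fold, and VSIG1, ALDH3A1 and IDH3G fell by 1.79, 1.47 and 1.28 on the log2 scale, though the ratios of the 3 kept probes of ALDH3A1 reached up to 0.08 on that array. On MHCC97L replicate 2 the largest increases included inflammatory genes. PTGS2, the inducible cyclooxygenase, was 31.7-fold higher, the collagenase gene MMP1 27.7-fold, the chemokine genes CCL20 and CXCL8 18.4-fold and 12.4-fold, and the cytokine gene IL1B 16.9-fold. The replication genes GINS2 and RRM2 fell by 2.91 and 2.56 on the log2 scale on that array. Across all genes the log2 ratios of the MHCC97L arrays correlated with Pearson's r = 0.336, against 0.588 between the MHCC97H arrays. MHCC97L replicate 1 correlated with r = 0.482 with MHCC97H replicate 1 and 0.649 with MHCC97H replicate 2, which was scanned on the same day. MHCC97L replicate 2, also scanned on that day, had r = 0.170 and 0.291 with these arrays.

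**Figure D1:**
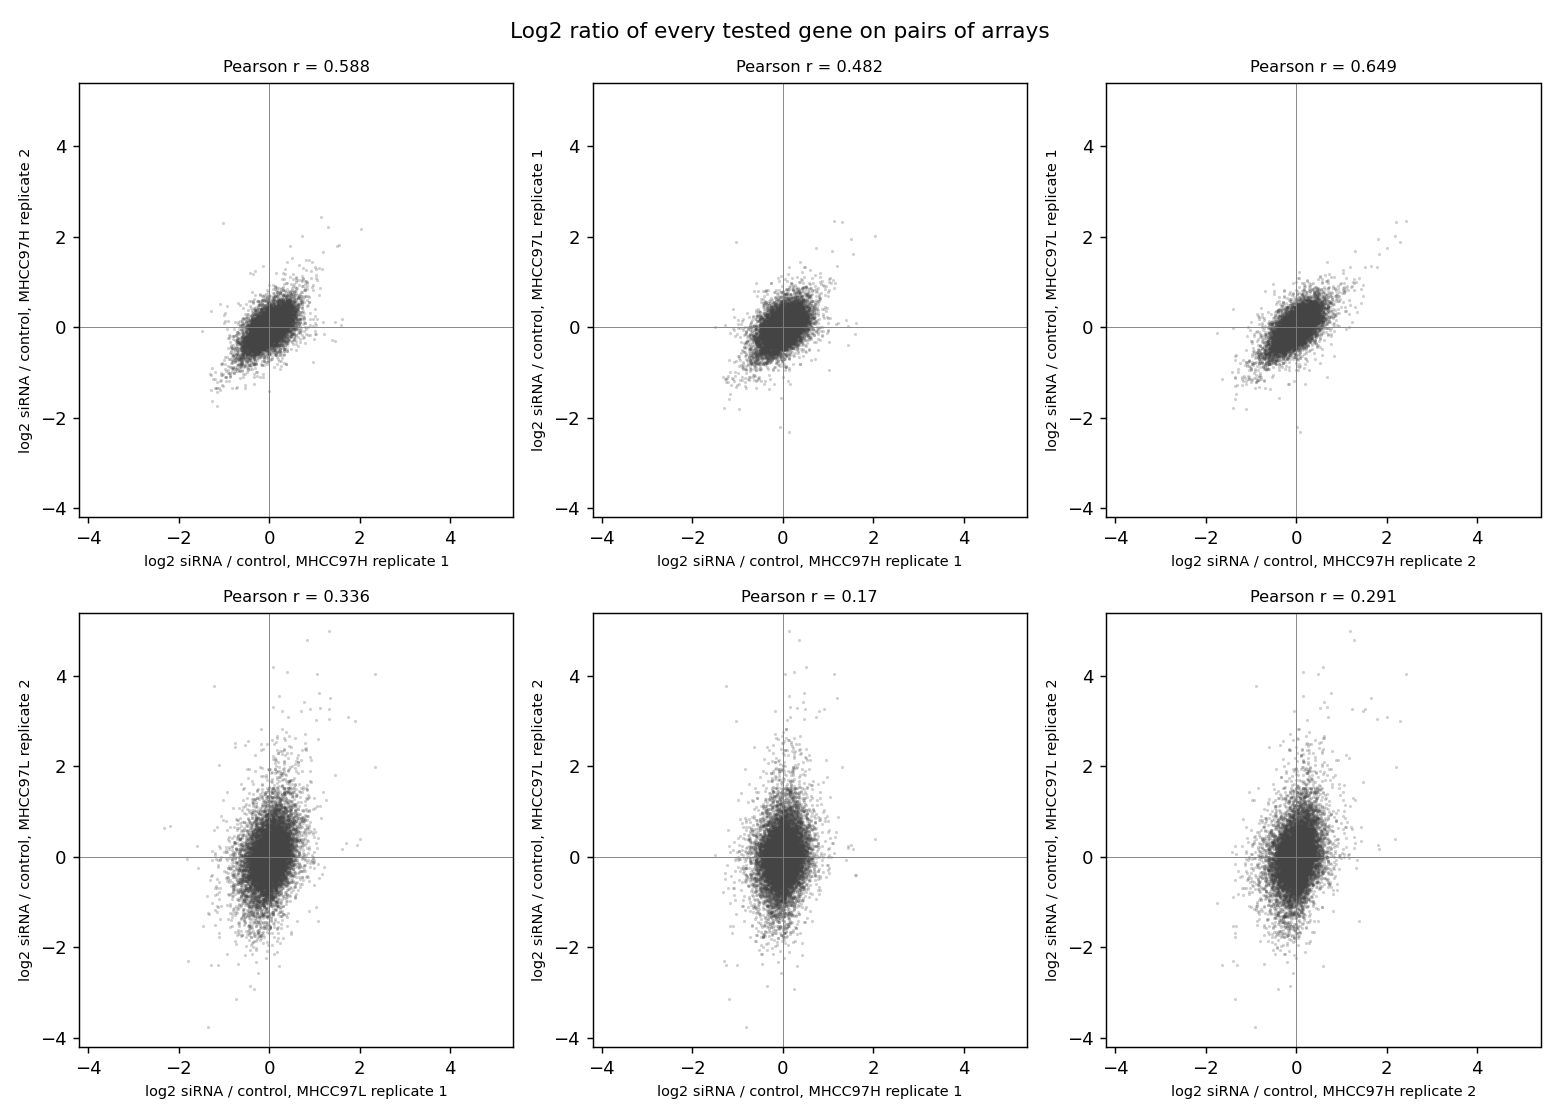
Each point is 1 of 11636 genes, with its log2 ratio of siRNA over control on 1 array on the horizontal axis and on another array on the vertical axis, for all 6 pairs of arrays. The clouds of the 3 pairs with MHCC97L replicate 2 are tall (r = 0.336, 0.170 and 0.291, SD of the ratios 0.614 on that array), and those of the other pairs are compact (r = 0.588, 0.482 and 0.649).

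In the fit over all 4 arrays limma called 0 genes in MHCC97L, with 2265 at an unadjusted p under 0.05 where 582 would be expected by chance and a smallest adjusted p of 0.174. Each MHCC97L array was therefore also fitted without the other one, which assumes that a lone array varies like the MHCC97H arrays and gives no check by a replicate. Gene list p-values from these fits with the preset correlation measure the spread across genes, not between replicates. MHCC97L replicate 1 then had 216 called genes, 87 higher and 129 lower, and MHCC97L replicate 2 had 4005, of which 2070 were higher and 1935 lower. These fits were used to name genes only after no gene had passed in the fit over all arrays. Replicates are named as the scanner files are. The authors' value table attaches the values that match each MHCC97L scanner file to the other MHCC97L sample, so which of the 2 MHCC97L samples is the one that stands apart is not settled. In both channels MHCC97L replicate 2 correlated no better with MHCC97L replicate 1 than with the MHCC97H arrays, so its line label is not borne out.

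On MHCC97L replicate 1 the other named increases were CD79A (5.03-fold), TCF7L2 (3.05-fold), COXFA4L3 (2.40-fold), SLC35C1 (1.79-fold), PDZK1IP1 (2.73-fold), MAP1LC3A (2.40-fold) and WBP2 (2.30-fold). The control signals of CD79A, TCF7L2, COXFA4L3 and SLC35C1 were not above background, so their folds are uncertain. A second probe of MAP1LC3A gave a log2 ratio of 0.14. FCER2 fell by 1.82, AGR2, a protein disulfide isomerase family member, by 1.32 and DDC, the aromatic amino acid decarboxylase, by 1.28. CALB2, DDX56 and the tight junction gene CLDN2 were 2.58-fold, 2.55-fold and 2.55-fold lower. Their siRNA signals were not above background, so these folds are uncertain. The adjusted p-values of the genes named for this array lay between 0.00574 and 0.0328. MAP1LC3A, DDX56, AGR2, ALDH3A1 and WBP2 had ratios of similar size on MHCC97L replicate 2 (1.26, -1.24, -1.26, -1.53 and 1.43), whereas FCER2 (-0.04), TCF7L2 (0.18) and SLC35C1 (-0.21) did not.

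On that array, 5 lists passed with the preset correlation. Mesenchymal and EMT genes (median 0.22 over 20 members, adjusted p = 0.0272, and adjusted p = 0.832 with an estimated correlation) had 2 rises, those of TGFBI (0.98) and FN1, fibronectin (0.88), and 0 falls, with 18 members not passing, CCN2 (-0.33) and TWIST1 (-0.24) among them. NF-kB and inflammatory genes (median 0.28 over 19 members, adjusted p = 0.0356, and adjusted p = 0.832 with an estimated correlation) had 3 rises, 0 falls and 16 not passing, CXCL8 (1.10, with a control signal not above background) among the rises and PTGS2 (1.32), LIF (-0.26) and CXCL5 (-0.23) not passing. NRF2 target genes (median 0.17 over 27 members, adjusted p = 0.0424, and adjusted p = 0.832 with an estimated correlation) had 1 rise, that of SOD2, the mitochondrial superoxide dismutase (1.06), 0 falls and 26 not passing, AKR1B10 (-0.76) lowest among these. Unfolded protein response genes went down (median -0.18 over 22 members, adjusted p = 0.0356, and adjusted p = 0.832 with an estimated correlation), with 2 falls, of HSPA5, the main chaperone of the endoplasmic reticulum (-1.16), and SDF2L1 (-0.81), 0 rises and 20 not passing, CALR (0.69) highest among these. Ribosomal protein genes had a median of 0.21 over 32 members (adjusted p = 0.0388, and adjusted p = 0.832 with an estimated correlation) with 0 members called. Adjusted over the list alone, the members up and down were 5 and 0, 4 and 0, 6 and 1, 0 and 5, and 0 and 0 in that order. Relative to the median of all genes, the NF-kB median of 0.28 was 0.10 with no filter on dim probes and 0.45 with plain subtraction of the background. With the deposited log ratio the medians were -0.10 for unfolded protein response, 0.29 for NRF2 target and 0.45 for ribosomal protein genes.

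MHCC97L replicate 2 had, beyond the inflammatory genes above, increases of MT2A (16.5-fold), SOD2 (16.4-fold), GDF15 (13.6-fold), a stress-induced cytokine, FBXO32 (11.8-fold), a ubiquitin ligase subunit, and COXFA4L3 (11.5-fold). GDF15 went the other way on the remaining arrays, with log2 ratios of -1.26 and -0.89 in MHCC97H and -1.21 on MHCC97L replicate 1. CLDN2 and ADH1A were 9.45-fold and 8.80-fold lower on MHCC97L replicate 2, SPTSSB 5.23-fold and NCAPG, a condensin subunit, 4.97-fold. Their siRNA signals, and the control signal of COXFA4L3, were not above background there, so these folds are uncertain. DKK1, a secreted Wnt inhibitor, fell by 2.85, DDC by 2.39, ENC1 by 2.37 and VSIG1 by 2.30 on the log2 scale. The adjusted p-values of the 20 genes lay between 3.05e-05 and 0.000296.

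The gene lists of that array showed the same contrast. Their p-values with the preset correlation measure the spread across genes on 1 array, and member calls take their spread from the MHCC97H arrays. Of 19 NF-kB and inflammatory genes, 17 rose, 1 fell and 1 did not pass (median 2.18, adjusted p = 6.6e-12, and adjusted p = 0.546 with an estimated correlation), led by PTGS2 and CCL20. CXCL5 (0.21) did not pass, and TNFAIP2 (-0.77), called lower, was not above background in either channel. Of 25 ATF4 and amino acid response genes, 21 rose, 1, SLC7A11 (-0.62), fell and 3 did not pass (median 1.16, adjusted p = 1.99e-10, and adjusted p = 0.546 with an estimated correlation). SESN2 (2.82) and ATF3 (2.68) led and SLC7A5 (-0.32) did not pass. Of 20 immediate early genes, 13 rose, 1, MYC (-0.62), fell and 6 did not pass (median 1.07, adjusted p = 1.62e-05, and adjusted p = 0.608 with an estimated correlation), with ATF3 and DUSP5 (2.50) highest. Of 24 matrix protease genes, 15 rose, 1, ADAM9 (-0.47), fell and 8 did not pass (median 0.70, adjusted p = 2.49e-05, and adjusted p = 0.546 with an estimated correlation). MMP1 and PLAT, tissue plasminogen activator (2.46), led, and MMP7 (-0.55) did not pass. Of 24 autophagy and lysosome genes, 17 rose, 0 fell and 7 did not pass (median 0.66, adjusted p = 3.25e-08, and adjusted p = 0.546 with an estimated correlation), with NPC1, a lysosomal cholesterol transporter (3.42), and WIPI1 (2.39) highest and BECN1 (-0.08) and ATG3 (0.02) not passing. Of 36 mitosis genes, 33 fell, 0 rose and 3 did not pass (median -1.29, adjusted p = 4.97e-16, and adjusted p = 0.546 with an estimated correlation), among them KIF23 (-1.85) and KIF20A (-1.80). CDC25B (0.45) and CENPA (0.21) did not pass. Of 36 S phase genes, 25 fell, 1 rose and 10 did not pass (median -1.27, adjusted p = 1.55e-12, and adjusted p = 0.546 with an estimated correlation), with GINS2 and RRM2 lowest. The rise was that of CCNE1, whose log2 ratio of 0.57 is not backed by a siRNA signal above background. Of 29 DNA repair genes, 16 fell, 1, ERCC1 (1.02), rose and 12 did not pass (median -0.58, adjusted p = 4.93e-05, and adjusted p = 0.546 with an estimated correlation), with EXO1 (-1.94) lowest. Adjusted over the list alone, members up and down numbered 17 and 1, 22 and 1, 13 and 1, 15 and 1, 18 and 0, 1 and 33, 2 and 29, and 2 and 19 in that order.

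With the preset correlation 17 of 37 lists passed on MHCC97L replicate 2 and 13 in the MHCC97L mean over both arrays, and none passed with an estimated correlation. In that mean, the largest median shifts were those of NF-kB genes (1.16, adjusted p = 8.88e-06), S phase genes (-0.70, adjusted p = 1.95e-07), mitosis genes (-0.68, adjusted p = 1.09e-07) and ATF4 genes (0.62, adjusted p = 0.000151). With an estimated correlation the adjusted p of each of these lists was 0.676. No member of these lists was called in that mean, and adjusted over the list alone 6 and 0, 0 and 0, 0 and 1, and 0 and 0 members were up and down. On MHCC97L replicate 1 the medians of these lists were 0.28, -0.12, 0.02 and 0.11. Without MHCC97L replicate 2, 5 lists passed in place of 13.

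**Figure D2:**
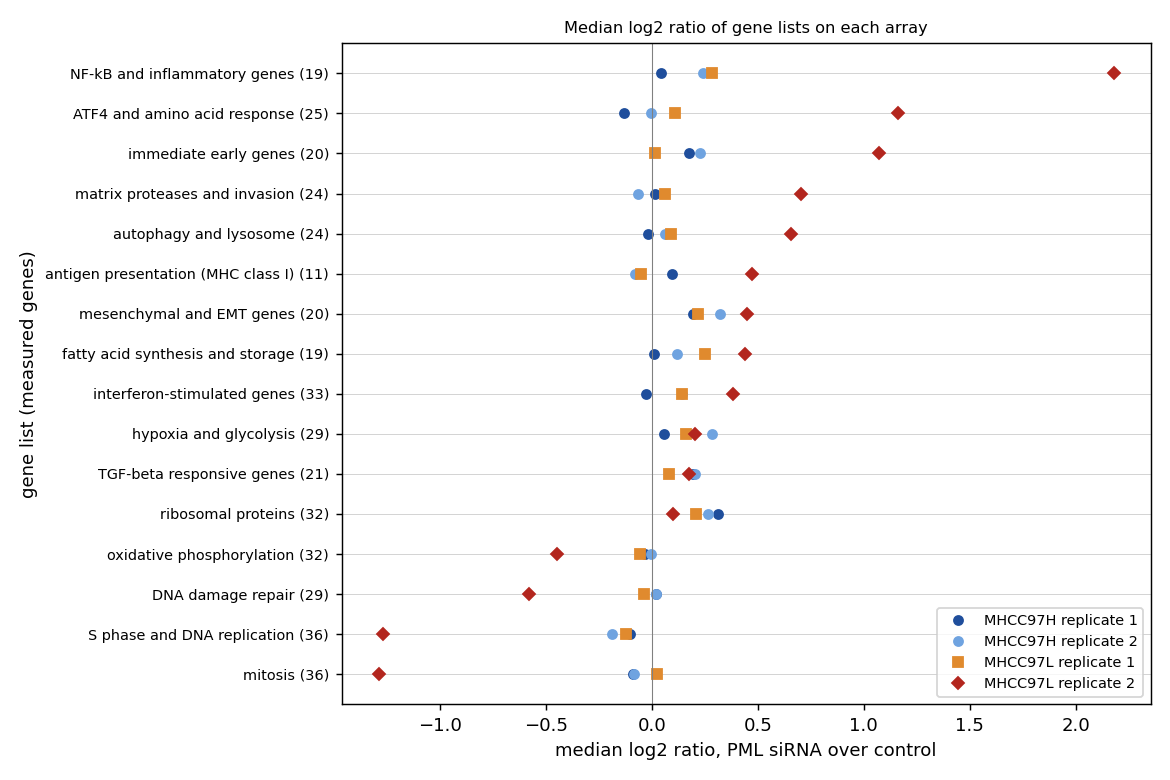
The horizontal axis gives the median log2 ratio of siRNA over control of the measured genes of 16 gene lists, with the number of measured genes in brackets, and each symbol is 1 array. MHCC97L replicate 2 lies apart from the other arrays for NF-kB and inflammatory genes (2.18 against 0.28 on MHCC97L replicate 1) and for mitosis genes (-1.29 against 0.02), and the MHCC97H arrays lie near MHCC97L replicate 1.

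The third comparison asks which changes were shared by both lines. MT2A was 5.61-fold higher over the 4 arrays, with MT1X at 3.72-fold and MT1B at 3.16-fold, and ENO2, NDRG1 and RND1 were 2.36-fold, 2.94-fold and 2.99-fold higher. CD79A (3.88-fold), COXFA4L3 (3.75-fold), TEX101 (2.61-fold) and CRABP2 (2.15-fold) completed the 10 increases. The largest decreases were those of VSIG1 (log2 ratio -1.69), SPTSSB (-1.61), ADH1A (-1.60), DDC (-1.50), ALDH3A1 (-1.37), MALL (-1.31), TM4SF4 (-1.24), POLE3 and CEP20 (-1.06 each) and FCER2 (-0.98). The control signal of CD79A was not above background on 1 array and that of COXFA4L3 on 3. The siRNA signal was not above background on 1 array for SPTSSB, ADH1A, CEP20 and FCER2 and on 3 for TM4SF4. The ratios of all these genes are therefore uncertain. POLE3 is a subunit of DNA polymerase epsilon. All 20 had the same sign on all 4 arrays and limma adjusted p-values between 0.000134 and 0.00563, with the line means as the 2 replicates. On MHCC97L replicate 2, TEX101 (0.27), CRABP2 (0.30) and FCER2 (-0.04) were much closer to 0 than on the other arrays. Others were larger there, among them NDRG1 (3.23, against 0.70 to 1.49 elsewhere), RND1 (3.27, against 0.91 to 1.24) and ADH1A (-3.14, against -0.73 to -1.34). The fold of such genes over the 4 arrays rests in good part on that array. Of 8 measured metallothionein genes, MT2A, MT1X, MT1B and MT1H passed in this test. MT1H (1.54) had a ratio of -1.02 on MHCC97H replicate 1, and MT1E (0.19), MT3 (0.24), MT1M (0.02) and MT1F (0.00) did not pass.

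Over line means limma called 307 genes, 148 higher and 159 lower. The count was 1647 without MHCC97L replicate 2 and 0 without MHCC97L replicate 1, and with spot means in place of spot medians, chosen after seeing the data, it was 0 as well. With the 4 arrays as independent replicates it was 40, and with line as a random block, genes changed in both lines numbered 110. The log2 ratios of the line means correlated across genes with Pearson's r = 0.462 and Spearman's rho = 0.429. Without MHCC97L replicate 1 these were 0.260 and 0.234, and without MHCC97L replicate 2 they were 0.637 and 0.585. Genes are not independent replicates. Between the fit of MHCC97H alone and MHCC97L replicate 1, 46 genes were higher in both where independent lists would share 3, and 99 were lower in both where 6 would be shared, with 1 gene opposite. These fits share the spread of the MHCC97H arrays. Between MHCC97H and MHCC97L replicate 2, 172 were higher and 192 lower in both, where 71.9 and 89.3 would be shared, and 28 and 66 went opposite ways.

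**Figure D3:**
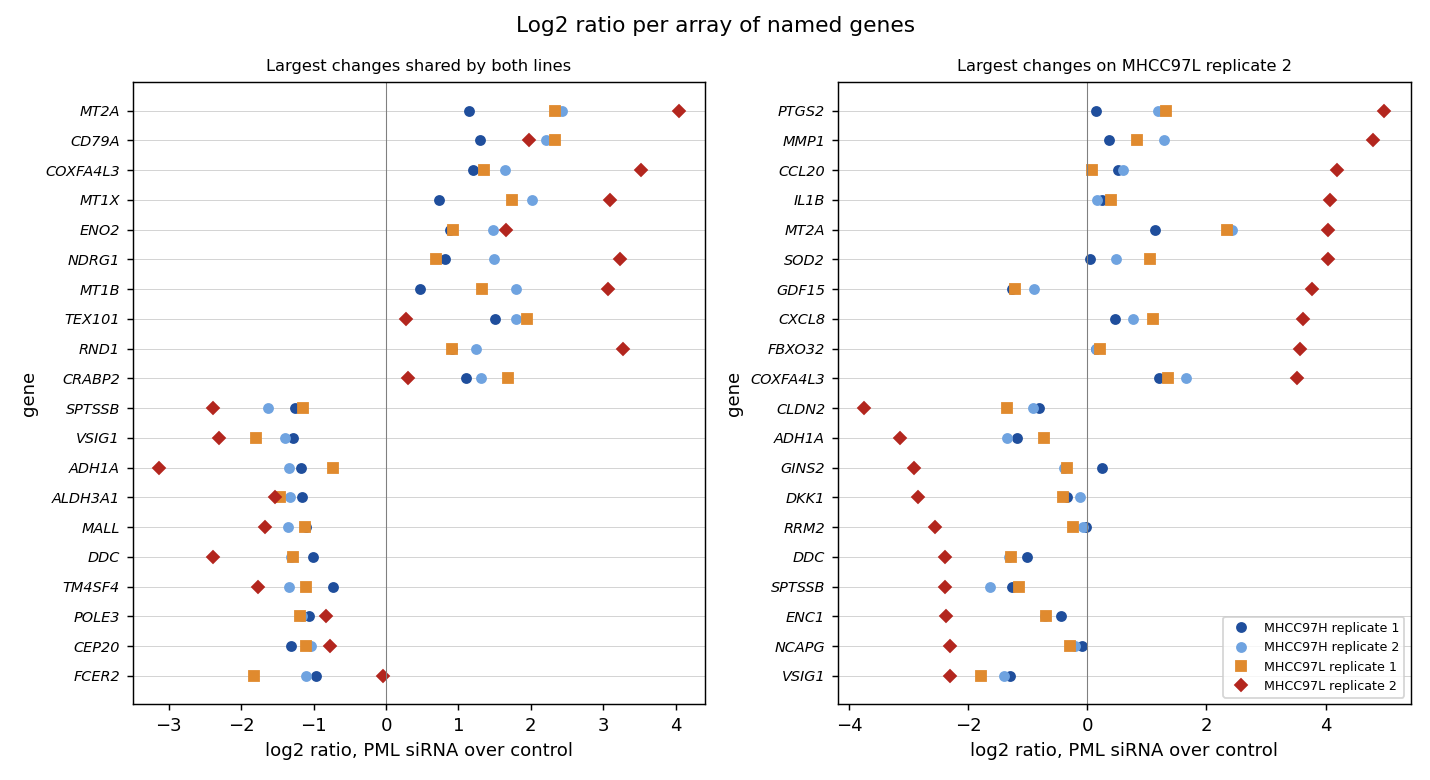
The horizontal axes give the log2 ratio of siRNA over control on each array, on the left for the 20 genes with the largest changes shared by both lines and on the right for the 20 with the largest changes on MHCC97L replicate 2. On the right, the ratios of MHCC97L replicate 2 (PTGS2 at 4.99, GINS2 at -2.91) lie outside those of the other 3 arrays for every gene shown.

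The last comparison asks where the lines differed. No single gene passed in the fit over all 4 arrays, in which limma called 0, with 395 at an unadjusted p under 0.05 where 582 would be expected by chance and a smallest adjusted p of 0.767. As lists, 11 differed with the preset correlation. ATF4 genes (median difference, MHCC97H minus MHCC97L, -0.73, adjusted p = 9.66e-07) and NF-kB genes (-1.06, adjusted p = 3.31e-06) were lower in MHCC97H, and mitosis genes (0.63, adjusted p = 9.66e-07) and S phase genes (0.49, adjusted p = 2.83e-05) were higher. With an estimated correlation, between 0.567 and 0.761 for these lists, the adjusted p was 0.785 for each. If genes are that correlated, the p-values with the preset correlation of 0.01 are far too small. No member of these lists passed, and adjusted over the list alone 0 were up and 0 down. Without MHCC97L replicate 2 only 1 list differed, that of mitochondrially encoded genes (-0.26 over 12 members, adjusted p = 0.00544, 0.850 as an adjusted p with an estimated correlation). Without MHCC97L replicate 2 the difference was called for 2 genes. These were ARMCX1 (2.18, adjusted p = 0.0152) and TRIM38 (2.44, adjusted p = 0.0128), both named after their values were seen. Their log2 ratios were -2.20 and -2.32 on MHCC97L replicate 1 and 0.68 and 0.65 on MHCC97L replicate 2. Without MHCC97L replicate 1 the count of differing genes was 2736. MHCC97H replicate 1 was scanned on another day than the other 3 arrays. A scan day block therefore takes up the difference between the MHCC97H arrays and leaves the spread to the MHCC97L arrays. It cannot separate day from array. With scan day as a block the counts of called genes were 0 in MHCC97H, 0 in MHCC97L and 0 for the difference. Within the second day, which leaves out MHCC97H replicate 1, they were also 0. The counts of shifted lists with that block were 4, 14 and 13, and the ribosomal protein list, at an adjusted p of 0.0261 for the difference without the block, did not pass with it (adjusted p = 0.0763).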

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

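Of the tests in this part, the camera test of the difference between the lines was planned, that of measurement noise was set before its value was seen, and the other tests of explanations were chosen after the results. Differences between the lines were found for 11 gene lists by the camera test of the difference with a preset correlation, which none passed with an estimated correlation. The few arrays limit the version with an estimated correlation. The median log2 ratio, MHCC97H minus MHCC97L, was -0.31 for interferon-stimulated genes, -0.34 for antigen presentation genes, 0.49 for S phase and DNA replication genes, 0.63 for mitosis genes, 0.33 for DNA damage repair genes, -0.34 for matrix proteases, 0.22 for oxidative phosphorylation genes, -0.73 for ATF4 genes, -1.06 for NF-kB genes, -0.47 for autophagy and lysosome genes and 0.14 for ribosomal proteins, the last of which did not pass with scan day as a block (adjusted p = 0.0763). Without MHCC97L replicate 2 none of these 11 differed by that test. A signal outside the main measurement appeared in 4 of 101 microRNA-named probes and 1399 of 9844 unnamed probes, which were above background in both channels on all 4 arrays, against 0 of 480 blank spots. The spots named for microRNAs were printed for short RNAs or their precursors, and the probe hsa-mir-220 had log2 ratios of -0.61, -0.78, -0.79 and -0.65, while those of the other 3 lay between -0.16 and 0.32.

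MHCC97L replicate 2 stands apart from the other 3 arrays, with an SD of log2 ratios of 0.614 against at most 0.313. Measurement noise as the whole source is argued against by the r of 0.71 between different probes of a gene on that array, where the others had 0.226 to 0.414. The SD of the difference between these probes was also highest there (0.47, against 0.346 to 0.384), so a share of added noise stays open. An altered control RNA as the whole source is argued against by r = 0.963 at least between its control channel and the other controls. This is above the highest r of 0.916 between its siRNA channel and the other siRNA channels. A first version of the control test, against the range of 0.964 to 0.982 among the other controls, left it undecided, so a smaller change of the control RNA stays open. MHCC97H siRNA RNA in its siRNA channel, as the whole source, is argued against by that r of 0.916, below the 0.965 or more among the other 3 siRNA channels of both lines, and a response of the MHCC97L line by a signed median of 0.135 on replicate 1 over the 4005 genes called on replicate 2 (median 0.746 there), but other versions of these tests left both undecided, and the line of the RNA (r = 0.902 with MHCC97L replicate 1) and a smaller share of a line response (0.0942 in MHCC97H) stay open. A separate siRNA RNA preparation may account for the pattern, since the siRNA RNA code in the file headers carries another letter on this 1 array than on the other 3, but with 1 such array preparation and array cannot be told apart.

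Changes shared by the other 3 arrays were weaker in the median on MHCC97L replicate 2, though not for each gene. Of the genes called in MHCC97H, 68.3% had the same sign on MHCC97L replicate 2 and 94.5% on MHCC97L replicate 1. Over the 941 genes called in MHCC97H the signed median was 0.476 on MHCC97L replicate 1 and 0.284 on replicate 2, a ratio of 0.596. A dye bias of the probes alone that acted alike on every array is argued against by that ratio. A dye bias that differed between arrays was not tested and stays open. siRNA and control RNA prepared in different batches on the 3 arrays could give changes that the array with equal letters lacks in part, and the signed median of 0.284 there leaves this open, since there is 1 such array and the meaning of the letters is not given in the sources used here. A response to PML loss that differed between transfections stays open as well and was not tested.

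The same genes changed in both lines, and without a dye swap a bias of single probes could give such agreement. Of the 307 genes called, 56 had a second kept probe, and for 55 of these it had the same sign, with a signed median 0.606 of that of the first probe. This argues against probe-specific dye bias as the whole source for these 56 genes. Values per array are not given. How far the agreement rests on MHCC97L replicate 2, where probes correlated best (r = 0.71, against 0.226 to 0.414 elsewhere), therefore stays open. For the 251 genes with 1 kept probe, TEX101 and CD79A among them, it could not be tested, and a bias that acts on a transcript as a whole stays open.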

How the results depend on the processing

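Spot means and loess within print blocks were chosen after seeing the data, as was the use of fits without an MHCC97L array to name genes. The other settings were planned. The cause of the changes below was not tested. The ratios of the brighter PML probe moved by less than the spread between arrays in every alternative run. This carries little weight, since PML was near background and leaving out 1 of 2 arrays cannot move their mean beyond their SD. The agreement of each line's arrays and the correlation between the lines moved by less than the SD of the between-line array correlations. That SD is wide (0.211), and the correlation of 0.462 was 0.260 without MHCC97L replicate 1 and 0.637 without MHCC97L replicate 2. With a trended and robust prior or scan day as a block, the counts of changed genes in each line and of genes differing between the lines stayed at 0. The scan day block takes its spread from the MHCC97L arrays alone and cannot separate day from array. The ratios as scanned moved the median of all genes to -0.19 on MHCC97L replicate 1 and 0.19 on MHCC97L replicate 2, so changes in them are relative to that shift. Signal over background limits PML and other dim genes, and the stricter filter on dim probes left PML without a value. The siRNA and control RNA of a pair share 1 array, so each ratio already pairs them and no further pairing was made.

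The number of genes changed in both lines, 307, was 52 with no background correction, 11 with plain subtraction (9 higher, 2 lower), 755 with median centring, 712 with scaling between arrays, 135 with the mean of the probes of a gene, 37 in the authors' value table (24 higher, 13 lower), 575 with the deposited log ratio, 0 with spot means, 565 with loess within print blocks, 55 with a log2 ratio of at least 1, 57 by size alone, 110 with line as a random block, 40 with 4 independent arrays, and 0 to 1647 when 1 array was left out. Of the 20 genes named for both lines, 20 no longer passed with spot means, 20 without MHCC97L replicate 1 and 14 with plain subtraction. The changed genes in MHCC97L, 0, became 39 with median centring, 4 with scaling, 244 by size alone and 0 to 4005 when 1 array was left out. The changed genes in MHCC97H, 0, became 941 in a separate fit, 56 by size alone and 0 to 941 when 1 array was left out. The genes differing between the lines, 0, became 109 by size alone and 0 to 2736 when 1 array was left out. Gene list shifts in MHCC97H, 4, became 7 with the deposited log ratio, 0 with an estimated correlation and 2 to 5 when 1 array was left out. Gene list shifts in MHCC97L, 13, became 0 and 5 to 17, and gene list shifts differing between the lines, 11, became 0 and 1 to 15, with an estimated correlation and when 1 array was left out. GDF15 in MHCC97L ranged from -1.21 without MHCC97L replicate 2 to 3.77, and SLC35C1 in MHCC97L from -0.21 without MHCC97L replicate 1 to 1.22.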

Other observations

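The gene lists were fixed before the data were examined, and the use of MHCC97L replicate 2 alone and the comparison of single channels were chosen after the results were seen. Several other gene groups moved on MHCC97L replicate 2 by the camera test with the preset correlation, whose p-values measure the spread across genes on 1 array. Of 33 interferon-stimulated genes, 15 rose and 1 fell (median 0.38, adjusted p = 0.000363, and adjusted p = 0.546 with an estimated correlation), led by IRF1 (1.95) and IFIH1 (1.78), and SAMD9 (-0.59) fell. Of 11 antigen presentation genes, 6 rose and 0 fell (median 0.48, adjusted p = 0.0182, and adjusted p = 0.546 with an estimated correlation), TAP1 (1.17) and HLA-B (1.00) highest. Of 22 unfolded protein response genes, 11 rose and 2 fell (median 0.50, adjusted p = 0.0153, and adjusted p = 0.546 with an estimated correlation), with PPP1R15A at 2.00 and DNAJB9 at 1.91, and with falls of SDF2L1 (-1.32) and CRELD2 (-0.96). Of 17 heat shock protein genes, 8 rose and 1 fell (median 0.42, adjusted p = 0.0191, and adjusted p = 0.546 with an estimated correlation), with CRYAB at 3.30 and HSPA1A at 1.81. Of 22 cholesterol synthesis genes, 9 rose and 2 fell (median 0.39, adjusted p = 0.0141, and adjusted p = 0.546 with an estimated correlation), with CYP51A1 at 1.35 and EBP at -1.06. Of 26 p53 target genes, 10 rose and 3 fell (median 0.20, adjusted p = 0.00646, and adjusted p = 0.546 with an estimated correlation), GDF15 (3.77) and SESN2 (2.82) highest and AEN (-1.11) lowest. Of 32 oxidative phosphorylation genes, 16 fell and 0 rose (median -0.45, adjusted p = 5.68e-05, and adjusted p = 0.546 with an estimated correlation), ATP5MC1 (-1.32) lowest. Of 11 stem and progenitor markers, 6 fell and 0 rose (median -0.51, adjusted p = 0.0196, and adjusted p = 0.546 with an estimated correlation), CD24 (-2.06) and ALDH1A1 (-1.70) lowest. Of 21 TGF-beta responsive genes, 9 rose and 2 fell (median 0.18, adjusted p = 0.0196, and adjusted p = 0.608 with an estimated correlation), with BHLHE40 at 2.09 and a fall of ID2 (-0.67). The members not passing numbered 17, 5, 9, 8, 11, 13, 16, 5 and 10 in that order. Adjusted over the list alone, members up and down numbered 15 and 1, 7 and 0, 12 and 2, 9 and 1, 11 and 2, 10 and 3, 1 and 17, 1 and 6, and 10 and 2. Some of these medians depended on the processing. Relative to the median of all genes, that of the stem and progenitor markers, of which 11 of 23 passed the filter, was -0.06 with no filter on dim probes. That of heat shock proteins was 0.15 with the mean of the probes of a gene and that of interferon-stimulated genes 0.61 with plain subtraction of the background. With the stricter filter on dim probes the medians were 0.94 for antigen presentation, 0.22 for unfolded protein response and 0.58 for TGF-beta responsive genes, and the latter was 0.32 with spot means.

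Markers of other cell types gave few values, with 5 fibroblast, 6 endothelial and 6 leukocyte genes measured. On MHCC97L replicate 2 their medians were 0.29, 0.29 and 0.08, and on MHCC97L replicate 1 they were -0.00, -0.02 and -0.02. The highest leukocyte marker was CD79A, which had positive ratios on all 4 arrays. CD68 (1.03) and the endothelial marker LYVE1 (0.56) also rose on MHCC97L replicate 2, and CD14 (-0.16) and CSF1R (-0.15) did not pass on MHCC97L replicate 2. Members of the list of PML nuclear body components had medians of 0.05, 0.02, 0.06 and 0.03 on the 4 arrays. In the fit of MHCC97H alone 1 of its 29 measured members, EP300 (0.64), rose and 2 fell, UBN1 (-0.42) among them, and on MHCC97L replicate 2 alone 7 rose and 5 fell. The list did not pass in either fit (adjusted p = 0.802 and 0.727).

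The single channels set the lines side by side. The control channel of MHCC97L replicate 2 correlated across 6685 genes with r = 0.969 and 0.981 with those of MHCC97H replicates 1 and 2. With that of MHCC97L replicate 1 its r was 0.963. The siRNA channel of MHCC97L replicate 2 had r = 0.907 and 0.916 with those of MHCC97H, and 0.902 with that of MHCC97L replicate 1. The control channel of MHCC97L replicate 1 had r = 0.964 with each MHCC97H control. The difference between MHCC97L and MHCC97H control channels, taken from separate arrays for each replicate, correlated with r = 0.225 in one pairing of the arrays and 0.00922 in the other, and in the siRNA channels with r = 0.0497 and -0.0148. The arrays therefore do not bear out the line label of MHCC97L replicate 2, and no explanation was tested for these values.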
